A study of Sus scrofa with 8 samples.

How the data were processed

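Per the labels, gene expression was measured in cultured porcine oviductal epithelial cells with 1-colour Affymetrix arrays after whole-transcript amplification and biotin labelling. The deposited values are log2 expression values, 1 per probe set and array. The authors made them with RMA, which corrects background, normalizes arrays to a common distribution and summarises probes, per the submitters' processing notes. The log2 scale was read from the values. A software version, the annotation build and any filter on probe sets are not given in the sources used here, nor whether normalization ran over these 8 arrays alone. This gives every array nearly the same distribution, so a shift of most genes in one direction would not show. No detection calls were used here, so genes at the floor of the arrays cannot be told from absent ones.

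Arrays were grouped by the time in their labels, with 2 arrays per time, and all 8 arrays were used. The number of pairs of arrays with identical values was 0. Probe sets were named through the platform annotation, with symbols checked by gene identifier against RefSeq genes of the Sscrofa11.1 assembly, used for names only. Of 27558 probe sets, 11968 had 1 gene symbol, 379 had several and were left out, and 15211 were unnamed here. Of those left out, 6 had a symbol and an identifier that named different genes. Identifiers of 11102 named probe sets matched genes of the assembly, and 1 symbol was updated. For the 966 genes with more than 1 probe set, the probe set with the highest mean over all arrays was kept. This left 10901 genes, 1086 of them under placeholder symbols, and list members outside them were not analysed here.

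Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) to the deposited values, without rescaling or filter. All 8 arrays entered a single model with 1 mean per time, which left 4 residual degrees of freedom. Comparisons were 7, 15 and 30 days each against 24h, 15 against 7 days and 30 against 15 days, later minus earlier, and a moderated F test covered the 4 times. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and a rise or fall is stated only of called genes. Errors are the SD between the 2 arrays of a time or the SE of a log2 change.

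The 25 gene lists covered motile cilia, oviductal secretory cells, epithelial adhesion and identity, squamous and basal keratins, fibroblast and mesenchyme, fibrillar collagens and collagen processing, smooth muscle and myofibroblast, mesothelium, endothelium, leukocytes and red blood cells. They also covered mitosis, DNA replication, p53 targets, immediate early and heat shock genes, cytokines and NF-kB targets, interferon response, and matrix proteases and the plasminogen system. The others were the TGF-beta pathway and targets, hypoxia and glycolysis, cholesterol synthesis, sex steroid and growth hormone receptors, the insulin-like growth factor system, the respiratory chain and cytosolic ribosomal proteins. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 125 tests of 25 lists and 5 comparisons. In the order of comparisons above, camera called 13, 15, 13, 11 and 11 lists. A preset correlation overstates evidence where members move together, so each call has an adjusted p with it estimated from the arrays. Under that estimate, imprecise from 8 arrays, camera called 0 lists, with 6, 8, 6, 6 and 6 at an unadjusted p under 0.05. Calls also ended at estimates below 0.01, so this does not show joint movement. Limma's fry, which tests whether members move on balance one way, called 19, 20, 19, 15 and 11. Counts adjusted over the list alone use Benjamini-Hochberg within that list.

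Genes were named by a rule. It took the 10 called genes with the largest increase and the 10 with the largest decrease in each comparison with 24h, 5 and 5 in the other comparisons, and up to 4 called members with the largest change of each list. Placeholder symbols were passed over 3 times, all among decreases from 15 to 30 days. Other genes are said to be chosen after their values were seen. Lists, rule, tests and alternatives were fixed before the data were examined. Alternatives for values were median centring, a further quantile normalization, leaving out the dimmest 25% of genes, the mean of a gene's probe sets and every probe set tested. Alternatives for the model were a trended, robust variance, only the 2 groups compared, the replicate number as a block, each array left out in turn and a change of at least 2-fold in addition. Lists were also tested with an estimated correlation and fry, and the overlap against 20 simulations of unchanged groups.

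The functions were tested on simulated data for 7 days against 24h over 10901 genes. All 100 genes changed by 2-fold and all 100 by 4-fold were called in the right direction, and 15 unchanged genes were called. A list lowered by 1 log2 unit was called, and 0 of 123 tests of unshifted lists were. The simulated noise was independent between genes, which real arrays need not be. Intervals in the closing section are 95% bootstrap percentile intervals over genes from 10000 draws, and cover the choice of genes, not the spread between arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.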

Results

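The series followed a primary culture of porcine oviductal epithelial cells, the cells that line the oviduct, through a month in vitro. Epithelium scraped from the oviducts of crossbred gilts was dispersed with collagenase and trypsin, and the pooled cells were grown in a medium with serum. Cultures were harvested after 24h and after 7, 15 and 30 days. Total RNA of each harvest was amplified, labelled with biotin and hybridised to Affymetrix whole-transcript arrays, 1 sample to an array. The 8 arrays make 4 groups of 2 arrays, 1 group for each time. The labels call the arrays of a time biological replicates and do not say whether they hold separate pools of cells. The p-values therefore measure only the spread between these samples, which may be technical. The comparisons ask how expression in the culture differed from that at 24h at each later time, and between successive later times.

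Each array gave 27558 probe set values, with array medians between 4.69 and 4.77 on the log2 scale. Across probe sets, which are not independent replicates, the arrays of a time correlated with r between 0.990 (24h) and 0.995 (15 days). Correlations with the 24h arrays were 0.952 to 0.958 at 7 days, 0.943 to 0.946 at 15 days and 0.921 to 0.925 at 30 days. Expression of 5048 of 10901 named genes (46.3%) differed over the 4 times in limma's moderated F test. The arrays lay in order of time along the leading principal component, which held 65.3% of the variance. The number of arrays limits the precision, and the median standard error of a comparison was 0.13 log2 units. At 24h, 76 genes lay more than 1 log2 unit apart between the arrays, against 8, 2 and 20 at 7, 15 and 30 days.

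**Figure D1:**
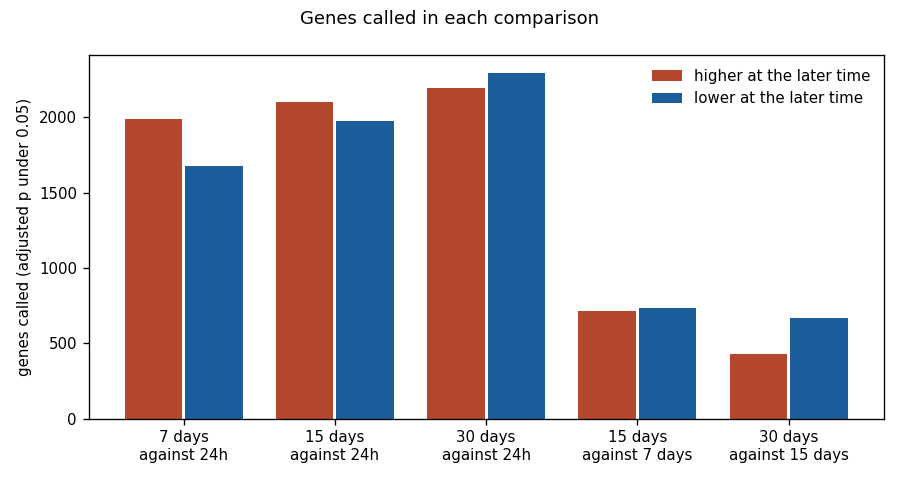
Number of genes called higher and lower at the later time in each comparison (limma, Benjamini-Hochberg adjusted p under 0.05, 2 arrays per time). Bars of the 3 comparisons with 24h stand between 1679 and 2297 genes, and those between later times between 430 and 733.

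Between 24h and 7 days, the interferon response list was called lower by camera (adjusted p = 0.242 with an estimated correlation). The fibroblast, collagen and mitosis lists were called higher (adjusted p = 0.168, 0.150 and 0.213 with an estimated correlation). OVGP1, which encodes the oviductal glycoprotein of this epithelium, fell 167-fold, from a log2 value of 11.12 ± 0.94 to 3.74 ± 0.20 (SD, n = 2, limma adjusted p = 5.3e-07). THY1, a surface glycoprotein of fibroblasts, rose 38.8-fold, from 3.88 ± 0.21 to 9.15 ± 0.086 (SD, n = 2, limma adjusted p = 6.6e-08). Of 41 measured mitosis genes, 39 rose. In all, 3669 of 10901 genes were called at this comparison, 1990 higher and 1679 lower, and 1078 of them differed by at least 2-fold.

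After THY1, the largest increases at 7 days, as log2 change ± SE, were those of LIPG, a lipase (5.19 ± 0.13), LOX, the lysyl oxidase that crosslinks collagen (4.86 ± 0.20), and ANKRD1, an ankyrin repeat protein (4.42 ± 0.50). COL1A2, a chain of type I collagen, rose by 3.96 ± 0.13. TMSB15A, a thymosin, rose by 3.83 ± 0.33, BST1, a cell surface enzyme, rose by 3.76 ± 0.15, and SGCE, a sarcoglycan, rose by 3.72 ± 0.14. FMOD, the collagen-binding proteoglycan fibromodulin, rose by 3.69 ± 0.11, and ITGB3, an integrin subunit, rose by 3.66 ± 0.12. After OVGP1 (-7.38 ± 0.34), the largest decreases were those of GCNT3, an enzyme of mucin glycosylation (-4.91 ± 0.14), and RSAD2, the interferon-induced viperin (-4.83 ± 0.20). FGFBP1, which binds fibroblast growth factors, fell by 4.80 ± 0.21, and SERPINB2, an inhibitor of plasminogen activators, fell by 4.60 ± 0.15. CD274, the immune checkpoint ligand PD-L1, fell by 4.50 ± 0.11, and GPX2, a glutathione peroxidase of epithelia, fell by 4.37 ± 0.18. OASL, an interferon-induced gene, fell by 4.25 ± 0.24, SLC28A3, a nucleoside transporter, fell by 3.75 ± 0.28, and TXNIP, a thioredoxin-binding protein, fell by 3.61 ± 0.16. Adjusted p-values of these 20 genes were at most 1.2e-04 in limma.

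Of 28 measured genes of epithelial adhesion and identity, 16 fell and 2 rose (17 and 3 adjusted over the list alone). The list's median change was -0.59 (camera adjusted p = 2.99e-04, adjusted p = 0.249 with an estimated correlation). EPCAM, an epithelial adhesion molecule, fell by 1.72 ± 0.14 (SE), GRHL2, a transcription factor of epithelia, fell by 1.62 ± 0.14, and CLDN7, a claudin of tight junctions, fell by 1.54 ± 0.19. Of 38 motile cilia genes, 16 fell and 2 rose (17 and 2 adjusted over the list alone). The median of the list was -0.26 (camera adjusted p = 6.97e-05, adjusted p = 0.201 with an estimated correlation). SPAG6 fell by 2.06 ± 0.15 and DNAH7 fell by 1.92 ± 0.25, both of which encode parts of the axoneme. Of 19 genes of oviductal secretory cells, 6 fell and 5 rose (6 and 5 adjusted over the list alone). Camera did not call the list (camera adjusted p = 0.483, median -0.091). MUC1, a membrane mucin, fell by 2.05 ± 0.14, and the complement gene C3 rose by 1.41 ± 0.16. Of 15 squamous and basal keratin genes, 5 fell and 4 rose (5 and 4 adjusted over the list alone). This list did not pass (camera adjusted p = 0.253, median -0.13). SERPINB5, a serpin of epithelia, fell by 2.50 ± 0.16, and ITGB6, an epithelial integrin subunit, rose by 1.13 ± 0.15.

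Of 23 fibroblast and mesenchyme genes, 14 rose and 1 fell (14 and 1 adjusted over the list alone). These members had a median of 0.99 (camera adjusted p = 5.68e-07, adjusted p = 0.168 with an estimated correlation), and 1.51 without the dimmest 25% of genes. FN1, which encodes fibronectin, rose by 3.05 ± 0.20 (SE), and MFAP5, a microfibril gene, rose by 2.83 ± 0.17. Of 21 genes of fibrillar collagens and collagen processing, 14 rose and 0 fell (15 and 0 adjusted over the list alone). This list had a median of 0.83 (camera adjusted p = 1.37e-07, adjusted p = 0.150 with an estimated correlation). COL1A1 rose by 3.02 ± 0.14 and PLOD2, a lysyl hydroxylase of collagen, rose by 2.64 ± 0.15. Of 16 smooth muscle and myofibroblast genes, 10 rose and 0 fell (11 and 0 adjusted over the list alone). The group median was 0.81 (camera adjusted p = 1.22e-04, adjusted p = 0.150 with an estimated correlation). ACTA2, the smooth muscle actin, rose by 2.39 ± 0.14, and TPM2, a tropomyosin, rose by 2.50 ± 0.21. Of 32 genes of the TGF-beta pathway and its targets, 17 rose and 2 fell (17 and 3 adjusted over the list alone). As a group their median was 0.47 (camera adjusted p = 1.06e-04, adjusted p = 0.322 with an estimated correlation). LTBP2, a matrix protein related to TGF-beta binding proteins, rose by 2.88 ± 0.15, and FST, the activin antagonist follistatin, fell by 2.76 ± 0.15. Markers of other cell types, measured beside these groups, were not called as lists: endothelium (1 of 18 rose and 3 fell, 1 and 3 adjusted over the list alone, camera adjusted p = 0.621) and mesothelium (3 of 8 rose and 2 fell, 3 and 2 adjusted over the list alone, camera adjusted p = 0.425). Nor were red blood cells (0 of 6 rose and 1 fell, 0 and 0 adjusted over the list alone, camera adjusted p = 0.846) and leukocytes (3 of 32 rose and 0 fell, 3 and 0 adjusted over the list alone, camera adjusted p = 0.578). The endothelial genes CD34 and KDR fell by 1.73 ± 0.16 and 1.69 ± 0.25. The leukocyte list passed as higher without replicate 2 of 24h (adjusted p = 0.00374, median 0.26), ranging from 0.00374 to 0.649 over alternatives at the preset correlation (adjusted p = 0.874 with an estimated correlation).

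Of 41 mitosis genes, 39 rose and 0 fell (40 and 0 adjusted over the list alone). Across the list the median was 1.72 (camera adjusted p = 4.59e-21, adjusted p = 0.213 with an estimated correlation). CENPF, a kinetochore protein, rose by 3.25 ± 0.34 (SE), and UBE2C, a ubiquitin-conjugating enzyme of mitosis, rose by 3.09 ± 0.37. DNA replication genes were not called as a list, the members going both ways (2 of 26 rose and 7 fell, 2 and 7 adjusted over the list alone, camera adjusted p = 0.164). PRIM1, a primase subunit, fell by 1.43 ± 0.17. The DNA replication list passed as lower without replicate 1 of 7 days (adjusted p = 0.0170, median -0.23), ranging from 0.0170 to 0.691 over alternatives at the preset correlation (adjusted p = 0.690 with an estimated correlation). Of 32 interferon response genes, 26 fell and 1 rose (28 and 1 adjusted over the list alone). Over these genes the median was -2.12 (camera adjusted p = 1.46e-16, adjusted p = 0.242 with an estimated correlation). IFIT1 fell by 3.57 ± 0.18 and IFI44 fell by 3.46 ± 0.23. Of 15 cholesterol synthesis genes, 13 rose and 1 fell (13 and 1 adjusted over the list alone). For the list the median was 0.84 (camera adjusted p = 9.82e-07, adjusted p = 0.245 with an estimated correlation). TM7SF2, a sterol reductase, rose by 2.91 ± 0.11, and INSIG1, a sterol-sensing regulator, rose by 1.97 ± 0.16. Of 23 hypoxia and glycolysis genes, 14 rose and 1 fell (14 and 1 adjusted over the list alone). In this group the median was 0.47 (camera adjusted p = 1.20e-04, adjusted p = 0.168 with an estimated correlation). PDK1, a pyruvate dehydrogenase kinase, rose by 2.28 ± 0.18, while ADM, the peptide adrenomedullin, fell by 1.60 ± 0.15.

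Of 14 p53 targets, 10 rose and 1 fell (10 and 1 adjusted over the list alone) at 7 days. Median change of the list was 0.78 (camera adjusted p = 3.27e-04, adjusted p = 0.150 with an estimated correlation). TP53INP1, a stress-induced protein, rose by 2.77 ± 0.21 (SE), RRM2B, a ribonucleotide reductase subunit, rose by 2.48 ± 0.17, and SESN2, a stress-induced sestrin, fell by 1.91 ± 0.13. Of 21 immediate early and heat shock genes, 13 fell and 2 rose (15 and 3 adjusted over the list alone). Members together had a median of -0.62 (camera adjusted p = 6.34e-05, adjusted p = 0.184 with an estimated correlation). FOSL1, an AP-1 subunit, fell by 2.06 ± 0.17. Of 25 respiratory chain genes, 9 rose and 0 fell (10 and 0 adjusted over the list alone). Taken over its members the median was 0.18 (camera adjusted p = 0.00603, adjusted p = 0.208 with an estimated correlation), and 0.29 without replicate 1 of 24h. NDUFA2, a subunit of complex I, rose by 1.69 ± 0.12. Lists that did not pass were cytokines and NF-kB targets (10 of 36 rose and 7 fell, 12 and 9 adjusted over the list alone, camera adjusted p = 0.244) and matrix proteases and the plasminogen system (7 of 24 rose and 4 fell, 7 and 4 adjusted over the list alone, camera adjusted p = 0.141). VCAM1 and ICAM1, adhesion molecules of the cytokine list, rose by 2.66 ± 0.31 and 2.21 ± 0.13, and CTSK, the collagenolytic cathepsin K, rose by 2.51 ± 0.10. Also not called were cytosolic ribosomal proteins (2 of 39 rose and 1 fell, 1 and 0 adjusted over the list alone, camera adjusted p = 0.409), of which RPL10 rose by 1.36 ± 0.27.

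**Figure D2:**
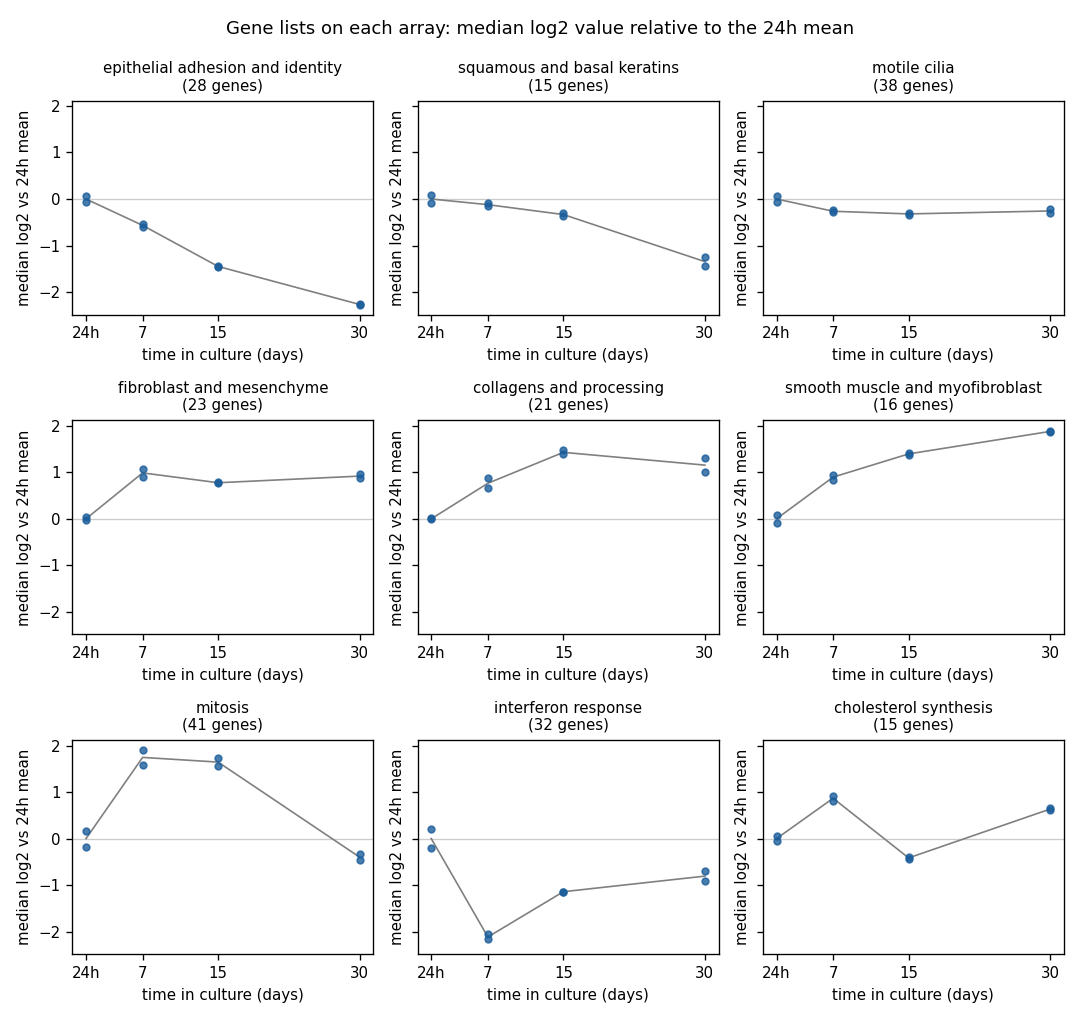
Median log2 value of the members of 9 gene lists on each array, relative to each gene's mean at 24h, against time in culture in days, where points are single arrays, 2 per time, and lines join their means. On the 30 days arrays the epithelial list lay at -2.26 and -2.28, and the mitosis list, at 1.91 and 1.58 on the 7 days arrays, lay at -0.34 and -0.46.

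At 15 days against 24h, camera called the collagen list higher (adjusted p = 0.150 with an estimated correlation) and the epithelial and interferon response lists lower (adjusted p = 0.150 and 0.347 with an estimated correlation). CHRDL1, a secreted antagonist of bone morphogenetic proteins, rose 70.4-fold, from a log2 value of 4.20 ± 0.13 to 10.34 ± 0.0036 (SD, n = 2, limma adjusted p = 1.2e-08). COL1A2 rose 56.4-fold to 10.86 ± 0.079 (SD, n = 2, limma adjusted p = 1.1e-08). MUC1 fell 28.8-fold, from 10.26 ± 0.028 to 5.41 ± 0.15 (SD, n = 2, limma adjusted p = 2.0e-08). In all, 4080 of 10901 genes were called at this comparison, 2103 higher and 1977 lower, and 1396 of them differed by at least 2-fold.

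The other largest increases at 15 days, as log2 change ± SE, were those of AGTR1, the angiotensin II receptor (5.46 ± 0.18), LOX (5.45 ± 0.20) and FMOD (5.39 ± 0.11). ENPP6, a choline phosphodiesterase, rose by 5.09 ± 0.21, THY1 rose by 5.03 ± 0.15 and SGCE rose by 4.87 ± 0.14. COL14A1, a fibril-associated collagen, rose by 4.85 ± 0.25, and FBN1, the microfibril protein fibrillin, rose by 4.78 ± 0.16. The largest decreases were those of OVGP1 (-7.71 ± 0.34), SERPINB2 (-6.30 ± 0.15) and FGFBP1 (-6.21 ± 0.21). CDA, cytidine deaminase, fell by 5.74 ± 0.16, ANKRD22 fell by 5.32 ± 0.21 and GCNT3 fell by 5.10 ± 0.14. GPX2 fell by 4.60 ± 0.18, CD274 fell by 4.49 ± 0.11 and OASL fell by 4.29 ± 0.24. Adjusted p-values of the 20 genes were at most 8.5e-07 in limma.

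Of 28 epithelial adhesion and identity genes, 21 fell and 3 rose (22 and 3 adjusted over the list alone) by 15 days. Their median log2 change was -1.42 (camera adjusted p = 2.21e-09, adjusted p = 0.150 with an estimated correlation). CLDN7 fell by 4.02 ± 0.19 (SE), AP1M2, an epithelial sorting adaptor, fell by 3.58 ± 0.18 and EPCAM fell by 3.38 ± 0.14. Of 15 squamous and basal keratin genes, 8 fell and 1 rose (8 and 1 adjusted over the list alone). The list's median change was -0.33 (camera adjusted p = 0.00243, adjusted p = 0.168 with an estimated correlation), and -0.84 without the dimmest 25% of genes. S100A14, a calcium-binding protein of epithelia, fell by 3.02 ± 0.15. Of 38 motile cilia genes, 15 fell and 1 rose (15 and 1 adjusted over the list alone). The median of the list was -0.26 (camera adjusted p = 3.18e-04, adjusted p = 0.227 with an estimated correlation). SPAG6 fell by 1.98 ± 0.15. Of 19 secretory cell genes, 6 fell and 5 rose (6 and 5 adjusted over the list alone). As a list they were not called (camera adjusted p = 0.450, median -0.28). CP, the copper-binding ceruloplasmin, rose by 4.38 ± 0.17 and C3 rose by 3.06 ± 0.16, while MUC1 fell by 4.85 ± 0.14.

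Of 23 fibroblast and mesenchyme genes, 13 rose and 1 fell (14 and 1 adjusted over the list alone) by 15 days. The median over members was 0.75 (camera adjusted p = 2.16e-08, adjusted p = 0.155 with an estimated correlation), and 1.61 without the dimmest 25% of genes. CDH11, a mesenchymal cadherin, rose by 4.61 ± 0.12 (SE). Of 21 collagen genes, 16 rose and 0 fell (16 and 0 adjusted over the list alone). These members had a median of 1.42 (camera adjusted p = 3.51e-10, adjusted p = 0.150 with an estimated correlation). COL5A2 rose by 4.35 ± 0.11. Of 16 smooth muscle and myofibroblast genes, 10 rose and 1 fell (12 and 1 adjusted over the list alone). This list had a median of 1.39 (camera adjusted p = 8.70e-06, adjusted p = 0.150 with an estimated correlation). ACTA2 rose by 3.65 ± 0.14, and ITGA8, an integrin of contractile mesenchyme, rose by 3.31 ± 0.18. Of 32 TGF-beta genes, 20 rose and 2 fell (20 and 2 adjusted over the list alone). The group median was 1.01 (camera adjusted p = 5.10e-06, adjusted p = 0.251 with an estimated correlation). LTBP2 rose by 4.20 ± 0.15 and FST fell by 3.72 ± 0.15. Lists of other cell types were not called: endothelium (2 of 18 rose and 2 fell, 2 and 2 adjusted over the list alone, camera adjusted p = 0.755) and mesothelium (2 of 8 rose and 0 fell, 2 and 0 adjusted over the list alone, camera adjusted p = 0.379). Neither were red blood cells (1 of 6 rose and 0 fell, 1 and 0 adjusted over the list alone, camera adjusted p = 0.846) and leukocytes (3 of 32 rose and 4 fell, 3 and 2 adjusted over the list alone, camera adjusted p = 0.154). CD34 fell by 1.98 ± 0.16. The leukocyte list passed as lower without replicate 1 of 24h (adjusted p = 4.37e-04), ranging from 4.37e-04 to 0.784 over alternatives at the preset correlation (adjusted p = 0.701 with an estimated correlation).

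Of 41 mitosis genes, 38 rose and 0 fell (38 and 0 adjusted over the list alone) by 15 days. As a group their median was 1.63 (camera adjusted p = 1.80e-18, adjusted p = 0.242 with an estimated correlation). KIF23, a kinesin of cytokinesis, rose by 2.83 ± 0.30 (SE). Of 32 interferon response genes, 24 fell and 1 rose (24 and 1 adjusted over the list alone). Across the list the median was -1.15 (camera adjusted p = 2.11e-09, adjusted p = 0.347 with an estimated correlation), and -0.73 without replicate 1 of 24h. RSAD2 fell by 3.38 ± 0.20. Of 21 immediate early and heat shock genes, 15 fell and 0 rose (16 and 0 adjusted over the list alone). Over these genes the median was -0.74 (camera adjusted p = 5.11e-06, adjusted p = 0.168 with an estimated correlation). FOSL1 fell by 2.97 ± 0.17. Of 14 p53 targets, 7 rose and 2 fell (8 and 2 adjusted over the list alone). For the list the median was 0.44 (camera adjusted p = 0.0170, adjusted p = 0.187 with an estimated correlation). TP53INP1 rose by 3.04 ± 0.21. Of 24 matrix protease and plasminogen system genes, 12 rose and 4 fell (13 and 4 adjusted over the list alone). In this group the median was 0.44 (camera adjusted p = 0.00887, adjusted p = 0.168 with an estimated correlation), and 0.80 without the dimmest 25% of genes. MMP2, a gelatinase, rose by 3.47 ± 0.12, and TIMP3, an inhibitor of such proteases, rose by 2.99 ± 0.13. DNA replication genes did not pass, with most members not called (2 of 26 rose and 7 fell, 2 and 7 adjusted over the list alone, camera adjusted p = 0.0523). MCM4, a subunit of the replicative helicase, fell by 1.35 ± 0.13. The DNA replication list passed as lower with values quantile normalized again (adjusted p = 0.0141), with only the 2 groups compared (adjusted p = 0.0476), without replicate 2 of 24h (adjusted p = 0.0162, median -0.41), without replicate 1 of 7 days (adjusted p = 0.0489), without replicate 2 of 7 days (adjusted p = 0.0474), without replicate 1 of 15 days (adjusted p = 0.0306) and without replicate 2 of 30 days (adjusted p = 0.0492), ranging from 0.0141 to 0.171 over alternatives at the preset correlation (adjusted p = 0.613 with an estimated correlation).

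Of 15 cholesterol synthesis genes, 9 fell and 1 rose (10 and 1 adjusted over the list alone) by 15 days. Median change of the list was -0.43 (camera adjusted p = 0.0180, adjusted p = 0.533 with an estimated correlation). ACAT2, an acetyl-CoA acetyltransferase, fell by 1.15 ± 0.10 (SE), while TM7SF2 rose by 1.84 ± 0.11. The cholesterol synthesis call ended without replicate 1 of 24h (adjusted p = 0.0598), and over alternatives at the preset correlation adjusted p ranged from 0.00872 to 0.0598. Of 39 ribosomal protein genes, 11 fell and 1 rose (11 and 1 adjusted over the list alone). Members together had a median of -0.22 (camera adjusted p = 0.0138, adjusted p = 0.418 with an estimated correlation). RPSA fell by 0.84 ± 0.19, while RPL10 rose by 2.15 ± 0.27. Of 25 respiratory chain genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone). Taken over its members the median was 0.13 (camera adjusted p = 0.0299, adjusted p = 0.260 with an estimated correlation). NDUFA2 rose by 1.28 ± 0.12. The respiratory chain call ended without the dimmest 25% of genes (adjusted p = 0.0892), without replicate 2 of 24h (adjusted p = 0.101) and without replicate 1 of 15 days (adjusted p = 0.0739), and over alternatives at the preset correlation adjusted p ranged from 0.0169 to 0.101. Lists that went both ways were hypoxia and glycolysis (5 of 23 rose and 6 fell, 5 and 6 adjusted over the list alone, camera adjusted p = 0.898, median -0.0056, mean -0.067 and test pointing up) and cytokines and NF-kB targets (11 of 36 rose and 11 fell, 12 and 11 adjusted over the list alone, camera adjusted p = 0.578). ADM fell by 2.44 ± 0.15, IL33, an alarmin cytokine, rose by 2.67 ± 0.22, and PTGS2, the inducible prostaglandin synthase, fell by 2.50 ± 0.16.

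By 30 days EPCAM had fallen 243-fold below 24h, from a log2 value of 11.23 ± 0.0078 to 3.31 ± 0.11 (SD, n = 2, limma adjusted p = 2.7e-09). MUC4, a membrane mucin, fell 175-fold, from 11.09 ± 0.24 to 3.64 ± 0.26 (SD, n = 2, limma adjusted p = 3.0e-09). LUM, the fibroblast proteoglycan lumican, rose 114-fold, from 3.83 ± 0.018 to 10.66 ± 0.14 (SD, n = 2, limma adjusted p = 5.5e-09). PRLR, the prolactin receptor, rose 73.1-fold, from 3.85 ± 0.19 to 10.04 ± 0.016 (SD, n = 2, limma adjusted p = 2.7e-09). In all, 4494 of 10901 genes were called at this comparison, 2197 higher and 2297 lower, and 1822 of them differed by at least 2-fold. With arrays median centred, 2409 were called higher and 2039 lower, so which direction held more genes changed with the scaling.

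Other large increases at 30 days, as log2 change ± SE, were those of CHRDL1 (6.42 ± 0.14), AGTR1 (6.29 ± 0.18) and DPP4, a cell surface peptidase (6.17 ± 0.14). FBN1 rose by 5.97 ± 0.16, COL1A2 rose by 5.94 ± 0.13, SGCE rose by 5.55 ± 0.14 and LOX rose by 5.54 ± 0.20. MYOZ2, a protein of the muscle Z-disc, rose by 5.58 ± 0.19, and its 2 probe sets gave 5.44 and 5.58. Other large decreases were those of OVGP1 (-7.49 ± 0.34), CDA (-6.96 ± 0.16), SERPINB2 (-6.92 ± 0.15) and SERPINB5 (-6.67 ± 0.16). FGFBP1 fell by 6.50 ± 0.21, and AQP9, an aquaglyceroporin, fell by 6.11 ± 0.19. APOBEC1, a cytidine deaminase that edits RNA, fell by 5.98 ± 0.20, and SPINT1, an inhibitor of epithelial serine proteases, fell by 5.96 ± 0.12. Adjusted p-values of the 20 genes were at most 1.3e-07 in limma. Some of these genes reached values near the floor of the arrays, below which 5% of probe sets lay at 2.66 to 2.74, so folds against them are compressed.

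Of 28 epithelial adhesion and identity genes, 25 fell and 1 rose (25 and 1 adjusted over the list alone) by 30 days. Their median log2 change was -2.26 (camera adjusted p = 8.99e-15, adjusted p = 0.150 with an estimated correlation). CLDN7 fell by 5.94 ± 0.19 (SE) and AP1M2 fell by 4.74 ± 0.18. The simple keratin genes KRT8, KRT18 and KRT19 were chosen after their values were seen. KRT8 stood at 11.05 ± 0.23 at 24h and 11.34 ± 0.16 at 30 days (SD, n = 2), a log2 change of 0.29 ± 0.14 that was not called (limma adjusted p = 0.148). KRT19 stood at 11.44 ± 0.023 and 11.28 ± 0.32 (SD, n = 2), a change of -0.16 ± 0.15 that was not called (limma adjusted p = 0.470), while KRT18 fell by 1.69 ± 0.17. Of 15 squamous and basal keratin genes, 11 fell and 0 rose (11 and 0 adjusted over the list alone). The list's median change was -1.30 (camera adjusted p = 1.67e-06, adjusted p = 0.150 with an estimated correlation). ITGB6 fell by 2.97 ± 0.15. Of 38 motile cilia genes, 14 fell and 2 rose (14 and 2 adjusted over the list alone). The median of the list was -0.25 (camera adjusted p = 0.00343, adjusted p = 0.280 with an estimated correlation). MYB, a transcription factor of multiciliated and dividing cells, fell by 2.06 ± 0.16. Of 19 secretory cell genes, 9 fell and 5 rose (9 and 5 adjusted over the list alone). Together they did not pass (camera adjusted p = 0.107, median -0.28). MUC1 fell by 5.56 ± 0.14 and CP rose by 4.80 ± 0.17. The secretory list passed as lower with fry (adjusted p = 0.00226) and without replicate 1 of 24h (median -0.52). It did not with an estimated correlation (adjusted p = 0.587).

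Of 23 fibroblast and mesenchyme genes, 13 rose and 1 fell (13 and 1 adjusted over the list alone) by 30 days. The median over members was 0.77 (camera adjusted p = 1.76e-07, adjusted p = 0.168 with an estimated correlation), and 1.39 without the dimmest 25% of genes. CDH11 rose by 5.28 ± 0.12 (SE). Of 21 collagen genes, 15 rose and 2 fell (16 and 2 adjusted over the list alone). These members had a median of 1.15 (camera adjusted p = 2.36e-07, adjusted p = 0.150 with an estimated correlation). COL14A1 rose by 5.28 ± 0.25 and COL8A1, a network-forming collagen, rose by 4.38 ± 0.12. Of 16 smooth muscle and myofibroblast genes, 11 rose and 1 fell (12 and 2 adjusted over the list alone). This list had a median of 1.88 (camera adjusted p = 1.28e-05, adjusted p = 0.150 with an estimated correlation). ACTA2 rose by 4.92 ± 0.14, and PLN, the calcium pump regulator phospholamban, rose by 3.46 ± 0.23. Of 32 TGF-beta genes, 20 rose and 4 fell (20 and 4 adjusted over the list alone). The group median was 0.60 (camera adjusted p = 9.65e-05, adjusted p = 0.322 with an estimated correlation). Lists of other cell types that were not called were endothelium (2 of 18 rose and 2 fell, 2 and 2 adjusted over the list alone, camera adjusted p = 0.691) and mesothelium (3 of 8 rose and 2 fell, 3 and 2 adjusted over the list alone, camera adjusted p = 0.482). The same held for red blood cells (1 of 6 rose and 1 fell, 1 and 1 adjusted over the list alone, camera adjusted p = 0.492) and leukocytes (1 of 32 rose and 12 fell, 1 and 12 adjusted over the list alone, camera adjusted p = 0.0958). CD34 fell by 1.72 ± 0.16 and SPI1, a transcription factor of myeloid cells, fell by 1.23 ± 0.28. C1QB, a complement gene of macrophages, stood at 6.50 ± 1.75 at 24h and 4.58 ± 0.00080 at 30 days (SD, n = 2, limma adjusted p = 0.0241). That call ended with a trended, robust variance model (adjusted p = 0.128), with only the 2 groups compared (adjusted p = 0.0579), without replicate 1 of 30 days (adjusted p = 0.0931) and without replicate 2 of 30 days (adjusted p = 0.0966), and over the alternatives its adjusted p ranged from 2.38e-06 to 0.128. The leukocyte list passed as lower without replicate 1 of 24h (adjusted p = 2.57e-04, median -0.31), ranging from 2.57e-04 to 0.327 over alternatives at the preset correlation (adjusted p = 0.672 with an estimated correlation).

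Of 26 DNA replication genes, 22 fell and 0 rose (25 and 0 adjusted over the list alone) by 30 days. As a group their median was -1.17 (camera adjusted p = 2.21e-09, adjusted p = 0.208 with an estimated correlation). MCM4 fell by 3.49 ± 0.13 (SE), and UHRF1, which maintains DNA methylation at replication, fell by 2.71 ± 0.18. Of 41 mitosis genes, 16 fell and 4 rose (19 and 5 adjusted over the list alone). Across the list the median was -0.40 (camera adjusted p = 0.0101, adjusted p = 0.672 with an estimated correlation), and -0.25 without replicate 2 of 24h. SPC25, a kinetochore protein, fell by 1.41 ± 0.15, while KIF23 rose by 2.83 ± 0.30. The mitosis call ended without replicate 2 of 24h (adjusted p = 0.131) and with fry (adjusted p = 0.125), and over alternatives at the preset correlation adjusted p ranged from 2.32e-04 to 0.131. Of 32 interferon response genes, 23 fell and 2 rose (23 and 2 adjusted over the list alone). Over these genes the median was -0.76 (camera adjusted p = 1.95e-06, adjusted p = 0.428 with an estimated correlation). HERC5, an interferon-induced ligase, fell by 2.61 ± 0.15. Of 21 immediate early and heat shock genes, 19 fell and 0 rose (20 and 0 adjusted over the list alone). For the list the median was -0.85 (camera adjusted p = 2.14e-08, adjusted p = 0.150 with an estimated correlation). DUSP5, a MAP kinase phosphatase, fell by 2.92 ± 0.13. Of 39 ribosomal protein genes, 23 fell and 1 rose (24 and 1 adjusted over the list alone). In this group the median was -0.40 (camera adjusted p = 8.02e-05, adjusted p = 0.249 with an estimated correlation). RPL36 fell by 1.03 ± 0.13, while RPL10 rose by 1.76 ± 0.27. Of 15 cholesterol synthesis genes, 10 rose and 1 fell (10 and 1 adjusted over the list alone). Median change of the list was 0.65 (camera adjusted p = 0.00164, adjusted p = 0.404 with an estimated correlation). INSIG1 rose by 1.86 ± 0.16.

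Lists not called at 30 days still held large single changes. Among them were p53 targets (7 of 14 rose and 2 fell, 7 and 2 adjusted over the list alone, camera adjusted p = 0.0598), of which CCNG1, a cyclin induced by p53, rose by 2.00 ± 0.11 (SE). The p53 target list passed as higher with fry (adjusted p = 5.08e-04) and a trended, robust variance model (adjusted p = 0.0413). It also did without replicate 1 of 24h (median 0.37), but not with an estimated correlation (adjusted p = 0.245). Others were cytokines and NF-kB targets (8 of 36 rose and 16 fell, 8 and 16 adjusted over the list alone, camera adjusted p = 0.483). CXCL8, a chemokine, fell by 4.88 ± 0.13, and CSF1, a macrophage growth factor, rose by 3.02 ± 0.11. Not called either were matrix proteases and the plasminogen system (9 of 24 rose and 8 fell, 10 and 8 adjusted over the list alone, camera adjusted p = 0.409), in which MMP2 rose by 4.26 ± 0.12 and MMP7, an epithelial matrix protease, fell by 3.94 ± 0.27. The remaining lists were hypoxia and glycolysis (7 of 23 rose and 7 fell, 7 and 7 adjusted over the list alone, camera adjusted p = 0.846, median 0.019, mean -0.031 and test pointing up) and respiratory chain (6 of 25 rose and 0 fell, 6 and 0 adjusted over the list alone, camera adjusted p = 0.119). HK2, a hexokinase, fell by 1.76 ± 0.25, and NDUFA2 rose by 1.22 ± 0.12.

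**Figure D3:**
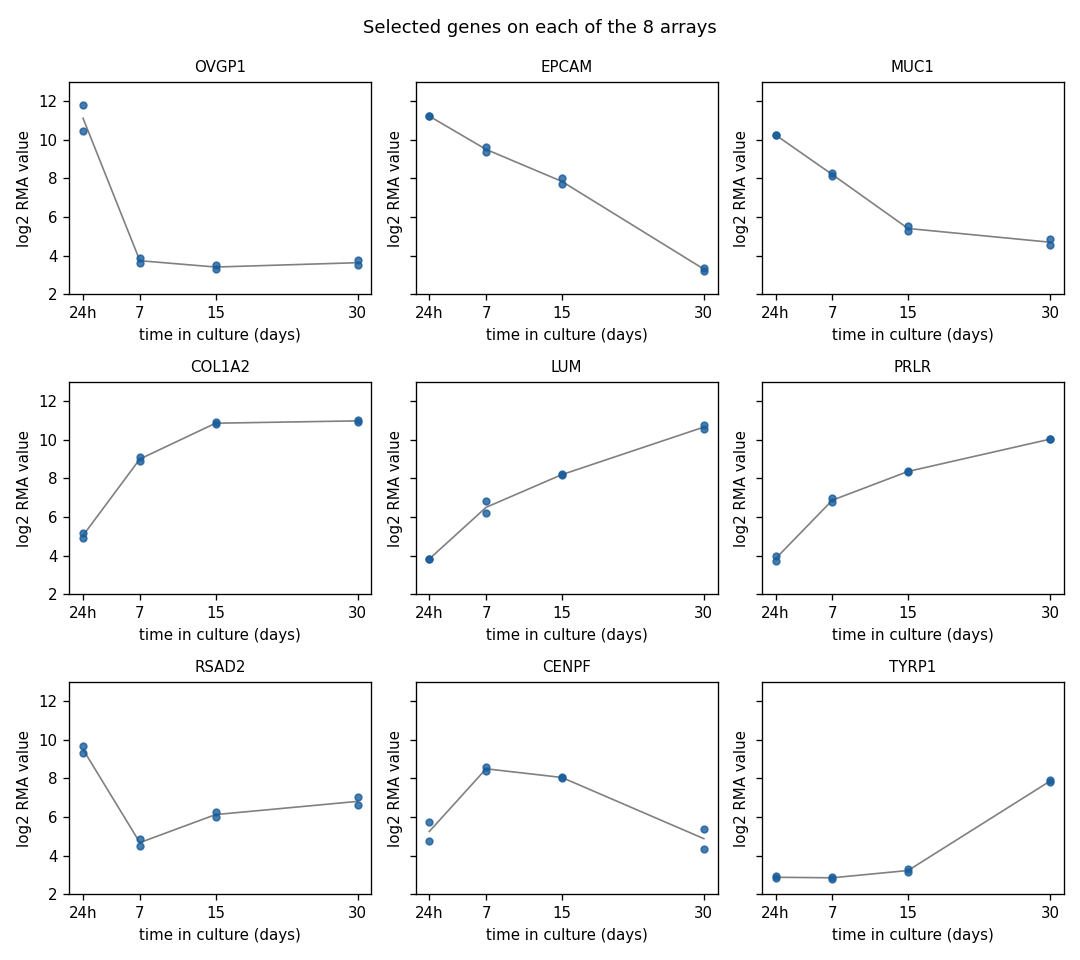
Log2 values of 9 genes on each of the 8 arrays against time in culture in days, where points are single arrays, 2 per time, and lines join their means. OVGP1 lay at 10.46 and 11.78 on the 24h arrays and between 3.31 and 3.88 on the other 6, and TYRP1 lay at 7.80 and 7.93 on the 30 days arrays and at 3.32 or below before.

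Between 7 and 15 days, camera called the cholesterol synthesis, hypoxia and glycolysis, and epithelial lists lower (adjusted p = 0.150, 0.150 and 0.150 with an estimated correlation). It called the collagen and interferon response lists higher (adjusted p = 0.150 and 0.347 with an estimated correlation). ENPP6 rose 25.0-fold, from a log2 value of 4.25 ± 0.17 to 8.90 ± 0.34 (SD, n = 2, limma adjusted p = 4.9e-06), and CDA fell 22.7-fold, from 8.73 ± 0.0064 to 4.22 ± 0.38 (SD, n = 2, limma adjusted p = 1.4e-06). The other largest increases, as log2 change ± SE, were those of CP (3.68 ± 0.17), IL33 (3.40 ± 0.22), VNN2, a vanin (3.39 ± 0.29), and TNFSF10, the death ligand TRAIL (3.35 ± 0.21). The other largest decreases were those of SDCBP2, a syntenin (-3.01 ± 0.11), PTGS2 (-2.89 ± 0.16), MUC1 (-2.79 ± 0.14) and AP1M2 (-2.59 ± 0.18). Adjusted p-values of the 10 genes were at most 8.6e-05 in limma. In all, 1450 of 10901 genes were called at this comparison, 717 higher and 733 lower, and 395 of them differed by at least 2-fold. The count was 633 without replicate 1 of 15 days, 668 without replicate 2 of 15 days and 899 without replicate 2 of 7 days, fits that leave a time with 1 array.

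Of 15 cholesterol synthesis genes, 14 fell and 0 rose (14 and 0 adjusted over the list alone) from 7 to 15 days. Members together had a median of -1.25 (camera adjusted p = 5.62e-19, adjusted p = 0.150 with an estimated correlation). STARD4, a sterol carrier, fell by 2.10 ± 0.18 (SE). Of 23 hypoxia and glycolysis genes, 15 fell and 0 rose (15 and 0 adjusted over the list alone). Taken over its members the median was -0.61 (camera adjusted p = 2.32e-10, adjusted p = 0.150 with an estimated correlation). HK2 fell by 1.98 ± 0.25, and PFKFB3, an activator of glycolysis, fell by 1.78 ± 0.13. Of 28 epithelial adhesion and identity genes, 20 fell and 2 rose (20 and 3 adjusted over the list alone). Their median log2 change was -0.89 (camera adjusted p = 3.70e-12, adjusted p = 0.150 with an estimated correlation). RAB25, a small GTPase of epithelia, fell by 2.14 ± 0.15. Of 15 squamous and basal keratin genes, 6 fell and 0 rose (6 and 0 adjusted over the list alone). The list's median change was -0.22 (camera adjusted p = 3.57e-04, adjusted p = 0.150 with an estimated correlation), and -0.52 without the dimmest 25% of genes. SFN, the epithelial protein stratifin, fell by 2.34 ± 0.15. Of 32 interferon response genes, 14 rose and 0 fell (16 and 0 adjusted over the list alone). The median of the list was 0.50 (camera adjusted p = 2.21e-09, adjusted p = 0.347 with an estimated correlation). IFI44 rose by 2.19 ± 0.23. Of 39 ribosomal protein genes, 1 fell and 0 rose (0 and 0 adjusted over the list alone). Members had a median change of -0.16 (camera adjusted p = 0.00953, adjusted p = 0.404 with an estimated correlation). The ribosomal protein call ended without replicate 2 of 7 days (adjusted p = 0.0991), and over alternatives at the preset correlation adjusted p ranged from 0.00189 to 0.0991.

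Of 21 collagen genes, 14 rose and 1 fell (14 and 1 adjusted over the list alone) from 7 to 15 days. The median over members was 0.62 (camera adjusted p = 1.28e-08, adjusted p = 0.150 with an estimated correlation). COL3A1 rose by 2.51 ± 0.17 (SE). Of 23 fibroblast and mesenchyme genes, 8 rose and 3 fell (11 and 3 adjusted over the list alone). These members had a median of 0.35 (camera adjusted p = 3.20e-04, adjusted p = 0.249 with an estimated correlation). PRRX1, a mesenchymal transcription factor, rose by 2.26 ± 0.15. Of 16 smooth muscle and myofibroblast genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone). This list had a median of 0.23 (camera adjusted p = 9.60e-04, adjusted p = 0.168 with an estimated correlation), and 0.38 without the dimmest 25% of genes. CNN1, calponin, rose by 1.86 ± 0.24. Of 32 leukocyte genes, 3 fell and 0 rose (0 and 0 adjusted over the list alone). The group median was -0.26 (camera adjusted p = 6.96e-04, adjusted p = 0.418 with an estimated correlation), and -0.54 without the dimmest 25% of genes. LCP1, an actin-bundling protein of white blood cells, went from 6.96 ± 0.19 to 5.33 ± 0.057 (SD, n = 2, limma adjusted p = 0.0219). Its adjusted p was 0.109 and 0.0808 without replicate 1 and 2 of 7 days, and 0.122 and 0.0985 without replicate 1 and 2 of 15 days, and ranged from 1.10e-04 to 0.122 over the alternatives. The leukocyte call ended with fry (adjusted p = 0.108), and over alternatives at the preset correlation adjusted p ranged from 1.09e-06 to 0.00566. Other cell types did not pass: endothelium (2 of 18 rose and 0 fell, 2 and 0 adjusted over the list alone, camera adjusted p = 0.877), mesothelium (2 of 8 rose and 1 fell, 3 and 1 adjusted over the list alone, camera adjusted p = 0.805, median -0.12, mean -0.0074 and test pointing up) and red blood cells (1 of 6 rose and 0 fell, 1 and 0 adjusted over the list alone, camera adjusted p = 0.592). PECAM1, an endothelial adhesion molecule, rose by 0.93 ± 0.13.

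Cell division lists did not pass from 7 to 15 days: mitosis (1 of 41 rose and 3 fell, 1 and 3 adjusted over the list alone, camera adjusted p = 0.450) and DNA replication (0 of 26 rose and 1 fell, 0 and 0 adjusted over the list alone, camera adjusted p = 0.262). The mitosis list passed as lower without replicate 2 of 7 days (adjusted p = 0.010, median -0.23), ranging from 0.010 to 0.920 over alternatives at the preset correlation (adjusted p = 0.891 with an estimated correlation). The DNA replication list passed as lower without replicate 2 of 7 days (adjusted p = 0.00930), ranging from 0.00930 to 0.825 over alternatives at the preset correlation (adjusted p = 0.746 with an estimated correlation). Also not called were motile cilia (1 of 38 rose and 1 fell, 1 and 1 adjusted over the list alone, camera adjusted p = 0.846, median -0.010, mean -0.031 and test pointing up) and oviductal secretory cells (5 of 19 rose and 4 fell, 7 and 5 adjusted over the list alone, camera adjusted p = 0.592), although MYB fell by 2.07 ± 0.16 (SE) and C3 rose by 1.64 ± 0.16. Neither were TGF-beta pathway and targets (7 of 32 rose and 3 fell, 8 and 3 adjusted over the list alone, camera adjusted p = 0.155), in which TGFB3 rose by 2.30 ± 0.26 and TGFBI, a matrix protein induced by TGF-beta, rose by 2.16 ± 0.24. The same was true of cytokines and NF-kB targets (3 of 36 rose and 7 fell, 4 and 7 adjusted over the list alone, camera adjusted p = 0.567, median 0.0034, mean -0.089 and test pointing down), with CXCL8 at -1.53 ± 0.13.

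Stress lists were not called from 7 to 15 days: immediate early and heat shock (2 of 21 rose and 5 fell, 3 and 6 adjusted over the list alone, camera adjusted p = 0.0509) and p53 targets (0 of 14 rose and 2 fell, 0 and 2 adjusted over the list alone, camera adjusted p = 0.162). DUSP5 fell by 1.17 ± 0.13 (SE), and PMAIP1, a p53-induced gene of cell death, fell by 1.14 ± 0.16. The immediate early list passed as lower with fry (adjusted p = 0.0160) and with arrays median centred (adjusted p = 0.0473). It did with a trended, robust variance model (adjusted p = 0.0308) and with only the 2 groups compared (adjusted p = 0.0492). It also did without replicate 1 of 24h and without replicate 2 of 30 days, but not with an estimated correlation (adjusted p = 0.404). The p53 target list passed as lower with fry (adjusted p = 0.0209) and without replicate 2 of 7 days (median -0.15). It did not with an estimated correlation (adjusted p = 0.346). Also not called were matrix proteases and the plasminogen system (7 of 24 rose and 3 fell, 7 and 3 adjusted over the list alone, camera adjusted p = 0.0683), with TIMP3 at 1.18 ± 0.13, and respiratory chain (0 of 25 rose and 1 fell, 0 and 0 adjusted over the list alone, camera adjusted p = 0.371). The matrix protease list passed as higher with fry (adjusted p = 0.00964) and the mean of a gene's probe sets (adjusted p = 0.0359). It also did without replicate 2 of 15 days (median 0.13), but not with an estimated correlation (adjusted p = 0.245).

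Between 15 and 30 days, camera called the mitosis, DNA replication and epithelial lists lower (adjusted p = 0.150, 0.150 and 0.150 with an estimated correlation) and the cholesterol synthesis list higher (adjusted p = 0.150 with an estimated correlation). TYRP1, a melanosomal protein of pigment cells, rose 24.8-fold, from a log2 value of 3.23 ± 0.12 to 7.87 ± 0.10 (SD, n = 2, limma adjusted p = 9.6e-08), and MMP7 fell 34.4-fold, from 9.79 ± 0.025 to 4.68 ± 0.75 (SD, n = 2, limma adjusted p = 4.6e-06). The other largest increases, as log2 change ± SE, were those of PLN (2.87 ± 0.23), PTGS2 (2.75 ± 0.16), HAND2, a transcription factor of reproductive tract stroma (2.75 ± 0.19), and C4H8orf46 (2.73 ± 0.14). The other largest decreases under gene symbols were those of MUC4 (-4.58 ± 0.16), EPCAM (-4.54 ± 0.14), PLET1 (-4.18 ± 0.21) and PCLAF, a partner of the replication clamp (-3.92 ± 0.40), whose 2 probe sets gave -3.92 and -2.82. Adjusted p-values of the 10 genes were at most 2.0e-04 in limma. In all, 1096 of 10901 genes were called at this comparison, 430 higher and 666 lower, and 356 of them differed by at least 2-fold. The count was 506 without replicate 1 of 15 days, 524 without replicate 2 of 15 days and 567 without replicate 2 of 30 days, fits that leave a time with 1 array.

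Of 41 mitosis genes, 39 fell and 0 rose (40 and 0 adjusted over the list alone) from 15 to 30 days. As a group their median was -1.83 (camera adjusted p = 1.71e-47, adjusted p = 0.150 with an estimated correlation). TOP2A, a topoisomerase, fell by 3.89 ± 0.24 (SE), and CDC20, an activator of the anaphase-promoting complex, fell by 3.33 ± 0.15. Of 26 DNA replication genes, 19 fell and 0 rose (22 and 0 adjusted over the list alone). Across the list the median was -0.74 (camera adjusted p = 5.11e-19, adjusted p = 0.150 with an estimated correlation). CCNE2, a cyclin of the G1 to S transition, fell by 2.43 ± 0.20. Of 28 epithelial adhesion and identity genes, 21 fell and 0 rose (24 and 0 adjusted over the list alone). Over these genes the median was -0.86 (camera adjusted p = 1.12e-21, adjusted p = 0.150 with an estimated correlation). SPINT1 fell by 3.60 ± 0.12. Of 15 squamous and basal keratin genes, 6 fell and 0 rose (8 and 0 adjusted over the list alone). For the list the median was -0.39 (camera adjusted p = 3.60e-06, adjusted p = 0.150 with an estimated correlation), and -0.26 without replicate 2 of 30 days. ITGB6 fell by 2.94 ± 0.15. Of 19 secretory cell genes, 6 fell and 0 rose (7 and 0 adjusted over the list alone). In this group the median was -0.082 (camera adjusted p = 0.00673, adjusted p = 0.382 with an estimated correlation), and -0.040 with arrays median centred and -0.15 without replicate 2 of 30 days. WFDC2, a secreted protein of reproductive epithelia, fell by 1.22 ± 0.15. The secretory call ended without replicate 1 of 30 days (adjusted p = 0.147), and over alternatives at the preset correlation adjusted p ranged from 1.07e-04 to 0.147. Of 15 cholesterol synthesis genes, 14 rose and 0 fell (14 and 0 adjusted over the list alone). Median change of the list was 0.98 (camera adjusted p = 1.46e-16, adjusted p = 0.150 with an estimated correlation). SC5D, a sterol desaturase, rose by 1.42 ± 0.13.

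Of 36 cytokine and NF-kB genes, 8 fell and 4 rose (12 and 4 adjusted over the list alone) from 15 to 30 days. Members together had a median of -0.11 (camera adjusted p = 0.00781, adjusted p = 0.168 with an estimated correlation), and -0.072 with arrays median centred and -0.20 without replicate 1 of 30 days. CXCL8 fell by 2.87 ± 0.13 (SE), while PTGS2 rose by 2.75 ± 0.16. Of 21 immediate early and heat shock genes, 6 fell and 0 rose (6 and 0 adjusted over the list alone). Taken over its members the median was -0.16 (camera adjusted p = 1.64e-04, adjusted p = 0.201 with an estimated correlation). IER3, an immediate early gene, fell by 1.30 ± 0.11. Of 39 ribosomal protein genes, 2 fell and 0 rose (2 and 0 adjusted over the list alone). Their median log2 change was -0.18 (camera adjusted p = 1.12e-04, adjusted p = 0.251 with an estimated correlation). Of 32 interferon response genes, 6 rose and 1 fell (10 and 2 adjusted over the list alone). The list's median change was 0.22 (camera adjusted p = 0.00283, adjusted p = 0.619 with an estimated correlation), and 0.35 without replicate 1 of 15 days, 0.12 without replicate 1 of 30 days and 0.37 without replicate 2 of 30 days. The interferon call ended without replicate 1 of 30 days (adjusted p = 0.0956) and with fry (adjusted p = 0.302), and over alternatives at the preset correlation adjusted p ranged from 6.71e-05 to 0.0956. Of 24 matrix protease and plasminogen system genes, 5 fell and 2 rose (7 and 4 adjusted over the list alone). The median of the list was -0.21 (camera adjusted p = 0.0372, adjusted p = 0.213 with an estimated correlation). MMP7 fell by 5.11 ± 0.27, while CTSK rose by 1.41 ± 0.10. The matrix protease call ended without the dimmest 25% of genes (adjusted p = 0.0853), with the mean of a gene's probe sets (adjusted p = 0.0744), without replicate 1 of 15 days (adjusted p = 0.0958) and without replicate 1 of 30 days (adjusted p = 0.0684), and over alternatives at the preset correlation adjusted p ranged from 0.0172 to 0.0958.

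Connective tissue lists were not called from 15 to 30 days: fibroblast and mesenchyme (5 of 23 rose and 3 fell, 6 and 4 adjusted over the list alone, camera adjusted p = 0.295, median -0.0054, mean 0.24 and test pointing up) and fibrillar collagens and collagen processing (1 of 21 rose and 5 fell, 2 and 6 adjusted over the list alone, camera adjusted p = 0.846, median 0.12, mean -0.034 and test pointing down). ASPN, the proteoglycan asporin, rose by 2.50 ± 0.18 (SE), LUM rose by 2.47 ± 0.18 and COL8A1 rose by 1.57 ± 0.12, while COL12A1 fell by 1.00 ± 0.14. Nor were smooth muscle and myofibroblast (3 of 16 rose and 0 fell, 4 and 2 adjusted over the list alone, camera adjusted p = 0.409, median -0.038, mean 0.24 and test pointing up) and TGF-beta pathway and targets (3 of 32 rose and 4 fell, 5 and 6 adjusted over the list alone, camera adjusted p = 0.943, median 0.051, mean -0.030 and test pointing down). ACTA2 rose by 1.27 ± 0.14, and GREM1, the antagonist gremlin, rose by 2.01 ± 0.26. Other lists without a call were motile cilia (1 of 38 rose and 1 fell, 1 and 0 adjusted over the list alone, camera adjusted p = 0.927, median 0.0069, mean -0.00015 and test pointing up), endothelium (0 of 18 rose and 1 fell, 0 and 1 adjusted over the list alone, camera adjusted p = 0.771, median 0.014, mean -0.063 and test pointing down) and leukocytes (0 of 32 rose and 1 fell, 0 and 1 adjusted over the list alone, camera adjusted p = 0.436). Further ones were mesothelium (1 of 8 rose and 2 fell, 1 and 2 adjusted over the list alone, camera adjusted p = 0.754, median 0.053, mean -0.057 and test pointing down) and red blood cells (0 of 6 rose and 0 fell, 0 and 0 adjusted over the list alone, camera adjusted p = 0.450). The last were hypoxia and glycolysis (1 of 23 rose and 3 fell, 4 and 3 adjusted over the list alone, camera adjusted p = 0.696), p53 targets (1 of 14 rose and 1 fell, 1 and 1 adjusted over the list alone, camera adjusted p = 0.450) and respiratory chain (0 of 25 rose and 1 fell, 0 and 0 adjusted over the list alone, camera adjusted p = 0.592). LDHA, lactate dehydrogenase, fell by 0.79 ± 0.11, and PLK2, a p53-induced kinase, fell by 0.93 ± 0.12.

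OVGP1, SERPINB2 and FGFBP1 were among the 10 largest decreases, and LOX, COL1A2 and SGCE among the 10 largest increases, in all 3 comparisons with 24h. Genes called in all 3 numbered 1306 higher and 1223 lower. Independent lists of these sizes would share 77.4 higher and 64.2 lower genes. The 2 arrays of 24h cannot be split, so part of the excess may come from the shared controls. Simulated unchanged groups, set against the same arrays, shared on average 0 limma calls each way. Such groups yield few calls, so this cannot size that part. A further 177 genes were called in opposite directions in a pair of these comparisons.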

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

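All alternatives given here were planned. The 80 values of genes with the largest changes, OVGP1 and TYRP1 among them, kept direction and call in 15 alternatives run on named genes. These leave out the test of every probe set and the added 2-fold change, run for counts alone. In at least 1 alternative, 62 of 489 values of rule-named genes lost their call and 0 reversed. With camera at the preset correlation, 8 of 125 list results did and 0 were called the other way, but some uncalled medians changed sign. Fry called the receptor list higher in every comparison (adjusted p at most 0.0152, median 0.029 at 7 days). Camera never called it and pointed down at 7 days (adjusted p = 0.977). The cause was not tested. With every probe set tested, 7304, 8183 and 9475 were called at 7, 15 and 30 days against 24h, 10122 in the F test and 4976 in all 3 comparisons with 24h (2529 with named genes), since more features were tested. A change of at least 2-fold in addition, stricter by construction, left 1078, 1396, 1822, 395 and 356 calls in the 5 comparisons and 698 in all 3 with 24h. With 1 array left out, the lone array of its time taken to vary like the others, calls ranged from 3005 to 3556 at 7 days, 2913 to 4165 at 15 days and 3778 to 4575 at 30 days against 24h. They ranged from 633 to 1583 for 15 against 7 days, 506 to 1211 for 30 against 15 days, 4393 to 4973 in the F test and 2018 to 2342 for the overlap. Called lists then ranged from 13 to 14, 15 to 16, 12 to 16, 10 to 13 and 8 to 11 in the 5 comparisons. Arrays share a replicate number with no stated common origin, and their deviations correlated with r of 0.0080 to 0.27 between times. With a replicate block 3804, 4196, 4613, 1532 and 1172 genes were called, and the DNA replication list passed as lower at 15 days against 24h (adjusted p = 0.0463, from 0.0141 to 0.171 over its alternatives at the preset correlation).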

Other observations

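In the 3 patterns weighed further on, the tests of cell makeup for the epithelial and interferon patterns, their repeats without single 24h arrays or over endothelial genes alone, the test of scaling against genes of like brightness and the test of single arrays for TYRP1 were chosen after the results were seen. PRLR, the prolactin receptor gene, rose by 3.03 ± 0.13, 4.52 ± 0.13 and 6.19 ± 0.13 log2 units (SE) at 7, 15 and 30 days against 24h in limma. ERBB3, a receptor of the epidermal growth factor family, changed by -1.89 ± 0.13, -3.01 ± 0.13 and -3.08 ± 0.13. The estrogen receptor gene ESR1 fell by 1.62 ± 0.14 by 7 days and rose by 1.25 ± 0.14 from 7 to 15 days. From 15 to 30 days its log2 change was -0.72 ± 0.14 (limma adjusted p = 0.0107), a call that ended without replicate 1 of 15 days (adjusted p = 0.0874), replicate 2 of 15 days (adjusted p = 0.0772) and replicate 2 of 30 days (adjusted p = 0.0913), over alternatives from 0.00357 to 0.0913. The retinoic acid receptor gene RARB rose by 2.40 ± 0.13, 2.43 ± 0.13 and 2.09 ± 0.13 at 7, 15 and 30 days against 24h. Camera did not call the list of sex steroid and growth hormone receptors against 24h at 7 days (4 of 18 rose and 5 fell, 4 and 5 adjusted over the list alone, camera adjusted p = 0.977, median 0.029, mean 0.068 and test pointing down), 15 days (6 of 18 rose and 4 fell, 6 and 5 adjusted over the list alone, camera adjusted p = 0.614) or 30 days (8 of 18 rose and 6 fell, 8 and 6 adjusted over the list alone, camera adjusted p = 0.483). Nor did it from 7 to 15 days (2 of 18 rose and 1 fell, 2 and 1 adjusted over the list alone, camera adjusted p = 0.247) or from 15 to 30 days (4 of 18 rose and 1 fell, 4 and 1 adjusted over the list alone, camera adjusted p = 0.425). Fry called the list higher each time.

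In the insulin-like growth factor system, IGFBP7, a secreted binding protein, rose by 2.69 ± 0.18, 3.92 ± 0.18 and 4.18 ± 0.18 log2 units (SE) at 7, 15 and 30 days against 24h in limma. PAPPA, a protease of binding proteins, rose by 2.85 ± 0.16, 2.62 ± 0.16 and 3.86 ± 0.16. The list was not called against 24h at 7 days (4 of 12 rose and 1 fell, 5 and 2 adjusted over the list alone, camera adjusted p = 0.145), 15 days (6 of 12 rose and 2 fell, 6 and 2 adjusted over the list alone, camera adjusted p = 0.0785) or 30 days (6 of 12 rose and 2 fell, 6 and 2 adjusted over the list alone, camera adjusted p = 0.0649). Fry called it higher at 7, 15 and 30 days (adjusted p = 0.00337, 6.81e-04 and 5.18e-04). At 15 days against 24h, the same list passed as higher without the dimmest 25% of genes (adjusted p = 0.0400, median 1.02), ranging from 0.0400 to 0.155 over alternatives at the preset correlation (adjusted p = 0.412 with an estimated correlation). At 30 days, the same list passed as higher without the dimmest 25% of genes (adjusted p = 0.0404, median 0.74), with a trended, robust variance model (adjusted p = 0.0492) and without replicate 1 of 30 days (adjusted p = 0.0268), ranging from 0.0268 to 0.104 over alternatives at the preset correlation (adjusted p = 0.404 with an estimated correlation). From 7 to 15 days, of 12 members 4 rose and 1 fell (6 and 1 adjusted over the list alone), and HTRA1, a secreted serine protease, rose by 1.30 ± 0.12. Members had a median change of 0.27 (camera adjusted p = 0.0224, adjusted p = 0.322 with an estimated correlation), and 0.47 without the dimmest 25% of genes. The growth factor call ended without replicate 1 of 7 days (adjusted p = 0.153), and over alternatives at the preset correlation adjusted p ranged from 0.0102 to 0.153. From 15 to 30 days the list was not called (1 of 12 rose and 1 fell, 1 and 1 adjusted over the list alone, camera adjusted p = 0.253).

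By 30 days the epithelial list was called lower and the fibroblast, collagen and contractile lists higher (adjusted p = 0.150, 0.168, 0.150 and 0.150 with an estimated correlation). A lower share of epithelial cells with all other cells in proportion was not decided. Among genes above the 24h median, 30 stromal members exceeded 13 endothelial and leukocyte members by a median of 2.30 log2 units at 30 days. The 95% interval was 1.53 to 3.60. Choosing lists called higher, and leukocyte genes by uneven 24h values, favours an excess. Of the 13, 10 were leukocyte genes (median -1.04), whose 24h arrays differed widely, and 3 endothelial genes (-0.49). The excess was 3.10 without replicate 1 of 24h, 1.69 without replicate 2 and 1.85 over the endothelial genes alone. Fewer epithelial cells as the whole of the OVGP1 fall by 7 days is argued against, since 27 epithelial members above the 24h median changed by a median of -0.55 (95% interval -0.71 to -0.25), against -7.38 for OVGP1. Replacement by stromal cells already present at 24h stays open: 24 of 27 such members (88.9%) fell by 30 days, yet KRT8 and KRT19 had log2 changes of 0.29 and -0.16, which were not called, against -7.93 for EPCAM, while KRT18 fell by 1.69 ± 0.17 (SE). In RNA of whole cultures it cannot be told apart from epithelial cells that lost EPCAM and held KRT8 and KRT19 transcripts, and time in culture, the factor of the design, may act through either.

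The interferon response list was called lower at 7 days, with a median log2 change of -2.12 (adjusted p = 0.242 with an estimated correlation). Loss of white blood cells present at 24h as the whole of the fall was tested with the 10 leukocyte genes above the median at 24h. Their median change was 0.24 (95% interval -0.020 to 0.62), which argues against it over both 24h arrays. FCER1G of macrophages, chosen after its values were seen, spread widely between those arrays (5.69 ± 1.59, SD, n = 2). Without replicate 1 of 24h that median was -0.56 (95% interval -0.86 to 0.092), beside -1.68 for the interferon list, and without replicate 2 of 24h it was 1.14 (95% interval 0.32 to 1.68), beside -2.35, so a smaller contribution stays open. A difference in scaling was not decided, since the arrays already shared nearly 1 distribution: rescaling left the list at -2.11 and -2.13, and other genes of like brightness, whose medians in 10 groups lay within 0.094 of 0, left it at -2.16 (95% interval -2.63 to -1.06). A response to isolation or early culture that had faded by 7 days may account for the fall, though not for the later change, since of 32 members 14 rose and 0 fell (16 and 0 adjusted over the list alone) from 7 to 15 days (median 0.50, adjusted p = 0.347 with an estimated correlation), a hypothesis that the design, with no sample before culture, leaves untested.

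TYRP1 rose between 15 and 30 days, as did OCA2, a melanosomal transporter, which stood at 3.70 ± 0.14, 4.06 ± 0.13, 5.18 ± 0.028 and 7.37 ± 0.25 at 24h, 7, 15 and 30 days (SD, n = 2, limma adjusted p = 1.8e-05 from 15 to 30 days), and TYRP1 at 2.88 ± 0.069, 2.85 ± 0.084 and 3.23 ± 0.12 at the first 3. Pigment cells at 30 days are argued against by a pigment cell list, drawn up after TYRP1 was seen. Of 17 other members, 1 rose and 3 fell (median log2 change 0.029, 95% interval -0.11 to 0.22). The 3, with SOX9, BLOC1S6 and HPS4, stood above the 24h median, so they say little of pigment cells. The abundant pigment genes PMEL, MLANA and DCT, like OCA2 and MITF, were chosen after their values were seen. PMEL, MLANA and DCT changed by 0.22 ± 0.11, 0.38 ± 0.15 and -0.11 ± 0.13 (SE) to at most 4.02, which was not called (limma adjusted p at least 0.158). A single deviant array is argued against, since TYRP1 on the lower 30 days array stood 4.57 log2 units above the 15 days mean. The member that rose was MITF, a transcription factor of pigment and other cells, which stood at 5.08 ± 0.26, 5.65 ± 0.10, 6.80 ± 0.0071 and 8.01 ± 0.075 at 24h, 7, 15 and 30 days (SD, n = 2), and what raised TYRP1 and OCA2 stays open.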
